A study of Mus musculus with 7 samples.

How the data were processed

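CTCF, a zinc finger protein that binds DNA at chromatin loop anchors and insulators, was mapped by chromatin immunoprecipitation and sequencing in naive B cells purified from mouse spleens by depletion of CD43-positive cells. There were 3 libraries from mice with 1 floxed Ctcf allele and 3 from mice with both alleles floxed, called fl/+ and fl/fl here. All of them carried the CD19-Cre knock-in, which drives recombination in B cells. The labels describe the libraries as biological replicates. An input library from fl/+ cells was sequenced as well, and its own signal was not analysed here.

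Each library came with its own peak list. The submitters' processing notes name cutadapt, BWA, SAMtools and MACS2, give no versions, and name the builds GRCm38 and GRCh38. The lists hold chromosomes of both species under separate prefixes, and only the mouse chromosomes entered the comparisons. Per the file format deposited, each line gives a summit, its fold enrichment over background as a ratio, and the −log10 of its p-value and q-value, all as the authors' peak caller wrote them. The lowest deposited −log10 q was between 1.00 and 1.01 in every list, and 17 to 36 peak numbers per list were missing from the numbering of the peak caller. Intervals with several summits span several lines, and each distinct interval was counted as 1 peak, represented by its summit with the highest fold enrichment.

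The depth of the libraries was read from the lists. MACS2's formulas link the fold enrichment and the Poisson p-value at a summit to a whole number of fragments and a local background, so both were solved from the deposited ratio and −log10 p. A solution within 0.002 of the printed −log10 p was found for 100% of the summits of each list, and the solver returned 100% of the fragments in simulated data. Relative to the input, the depth was 1.08, 1.03 and 0.741 in fl/+ replicates 1 to 3. It was 0.671, 1.01 and 0.675 in fl/fl replicates 1 to 3. The background of all 6 lists corresponded to an input of the same depth. The absolute number of reads is not given in the sources used here. As each list holds both species, this depth is that of both together, and the mouse part of it is not known. fl/+ replicates 1 and 2 and fl/fl replicate 2 were thus deeper than the input and the others shallower, a split that does not follow the genotypes. Comparisons of peak numbers and covered lengths are given within these depth classes beside the pooled ones, a choice made after the data had been seen.

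Peaks of the 6 libraries that overlapped by at least 1 bp were merged into sites, and a site counted as called in a library when a peak of that library lay in it. Sites called in all 3 fl/+ libraries are called reference sites. Peak numbers, covered lengths and shares of peaks were compared with exact two-sided permutation tests over the 20 labellings of the 6 libraries, whose smallest p is 0.1. For recovery, each fl/+ library was held out in turn, and the sites called in both others were looked up in the held-out library and in each fl/fl library. That test was one-sided, with a smallest p of 0.05. Overlap within and between genotypes was compared on lists of equal length by Jaccard index over the 10 splits, with a smallest p of 0.1. With 3 libraries against 3, most of these tests cannot pass 0.05.

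Genes were taken from a RefSeq table of GRCm38.p6 with 49997 genes, which gives the start and end of each gene and no strand. The planned share of peaks at transcription starts was therefore replaced by the share of summits within 1 kb of either end of an annotated gene, and exons and introns were not told apart. The planned search for the CTCF motif needs a genome sequence and was not run. For 16 gene lists, the share of their reference sites called per fl/fl library was set against 10000 random sets of reference sites matched in 10 bins of mean fl/+ fold enrichment, drawn with replacement from sites outside the list, with Benjamini-Hochberg adjustment over the lists. A reference site belonged to a list when its summit lay in a member gene or within 10 kb of it. Sites are not replicates, so these tests describe the libraries. In simulated calls at 4000 sites, 4% of 200 random lists of 20 sites had p under 0.05, as did 100% of lists with 8 emptied sites. The recovery test reached its smallest p in 6.5% of 200 simulations without a difference and in 100% of those with fewer fl/fl calls. Simulated libraries of a genotype shared the same calling limit, unlike the real lists, so the 100% does not give the power in these data.

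The lists, the tests and the rule for named genes were chosen before the data were examined. The rule named the sites of the Ctcf gene, in each list the genes with the strongest reference sites and those called in fewest fl/fl libraries, the 10 strongest sites called in every fl/+ and no fl/fl library, up to 10 of the mirror class, and the 5 strongest sites called in all 6 libraries. A site was tied to the gene that holds its middle, or to the gene end nearest to it.

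Alternatives were a −log10 q of at least 5, a fold enrichment of at least 5, a reciprocal overlap of 50%, and summits within 100 bp. Others were lists of equal length, scaling to equal background, other gene distances, each library left out, and pairs by replicate number. Scaling to equal background brought each list to the lowest background of any list, which is set by depth and fragment length together. For the pairs, the correlation of the deviations of same-numbered libraries from their genotype means was computed over sites. It was 0.183, 0.352 and 0.203 for calls, over the limit of 0.1 for each number. Over relative signal it was −0.12, 0.23 and 0.22, so the first pair did not vary together there. Differently numbered libraries also passed the limit. Over calls, fl/+ replicate 3 with fl/fl replicate 1 reached 0.101, and the other such pairs lay at −0.286 to 0.096. Over relative signal, fl/+ replicate 1 with fl/fl replicate 2 reached 0.369, above every same-numbered pair, and the others lay at −0.357 to 0.123. These correlations therefore do not establish a pairing. The replicate numbers follow the order of the samples and no label ties them to a litter or a day. The unpaired comparison was kept as the main one.

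After the data had been seen, the relative CTCF signal was compared at 11498 summits called in every library, with summits widened by 50 bp to either side before merging. Solved fragments divided by depth were put on a log2 scale with no pseudocount, centred on the median of each library, and tested with limma 3.58.1 in R 4.3.3 with a trended prior and Benjamini-Hochberg adjustment. In data simulated for 3 fl/+ and 3 fl/fl libraries at these summits, it recovered 34% of 100 summits changed by 1.0 on the log2 scale and 1% of 100 changed by 0.5, with 0 false calls. The simulated noise was independent between summits and equally wide in each library. The real libraries differed in depth, so neither these shares nor the 0 false calls carry over to them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.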

Results

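CTCF occupancy was profiled by chromatin immunoprecipitation and sequencing in naive splenic B cells of mice carrying CD19-Cre with 1 floxed Ctcf allele (fl/+, 3 libraries) or with both alleles floxed (fl/fl, 3 libraries). The comparison asks which CTCF binding sites remain occupied when both alleles are targeted in B cells. Relative to the input, the depth was 1.08, 1.03 and 0.741 in fl/+ replicates 1 to 3, and 0.671, 1.01 and 0.675 in fl/fl replicates 1 to 3. Merging all peaks gave 66662 sites on the mouse chromosomes, with a median width of 350 bp. All coordinates are on GRCm38, and fold enrichments are the authors' own values for each list, which describe and rank sites within a list and are no measure of change between libraries.

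At the Ctcf gene itself (chromosome 8, 105636474 to 105682922), the sites at both ends of the gene were called in all 6 libraries. The site over its start (105636159 to 105637682) had fold enrichments of 61.2, 48.2 and 16.9 in fl/+ replicates 1 to 3, and of 5.21, 34.2 and 6.67 in fl/fl replicates 1 to 3. The site past its other end (105685416 to 105686596) had fold enrichments of 74.9, 58.2 and 19.2 in fl/+ and of 8.14, 41.4 and 10.9 in fl/fl. A weaker site inside the gene (105660990 to 105661740) was called in the 3 fl/+ libraries, at 18.3, 10.2 and 4.03. Among the fl/fl libraries it was called in replicate 2 alone, at 8.87. The labels do not place the loxP sites, so these sites do not check the deletion.

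Fewer CTCF peaks were listed in fl/fl than in fl/+ B cells on average, but the libraries of each genotype spread widely. The fl/+ lists held 63776, 53217 and 27960 peaks, 48318 ± 18404 (SD, n = 3). The fl/fl lists held 13168, 44148 and 14844 peaks, 24053 ± 17423 (SD, n = 3). The ratio of the geometric means, fl/fl over fl/+, was 0.45 (exact two-sided permutation test, p = 0.2, smallest possible 0.1), so the test did not set the difference apart from the spread between replicates. In each pair of same-numbered libraries the fl/fl list was the shorter and covered less, which gave p = 0.25 in an exact sign-flip permutation test, the smallest that 3 pairs allow. Within the deeper libraries the ratio was 0.758, and within the shallower libraries it was 0.5.

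**Figure D1:**
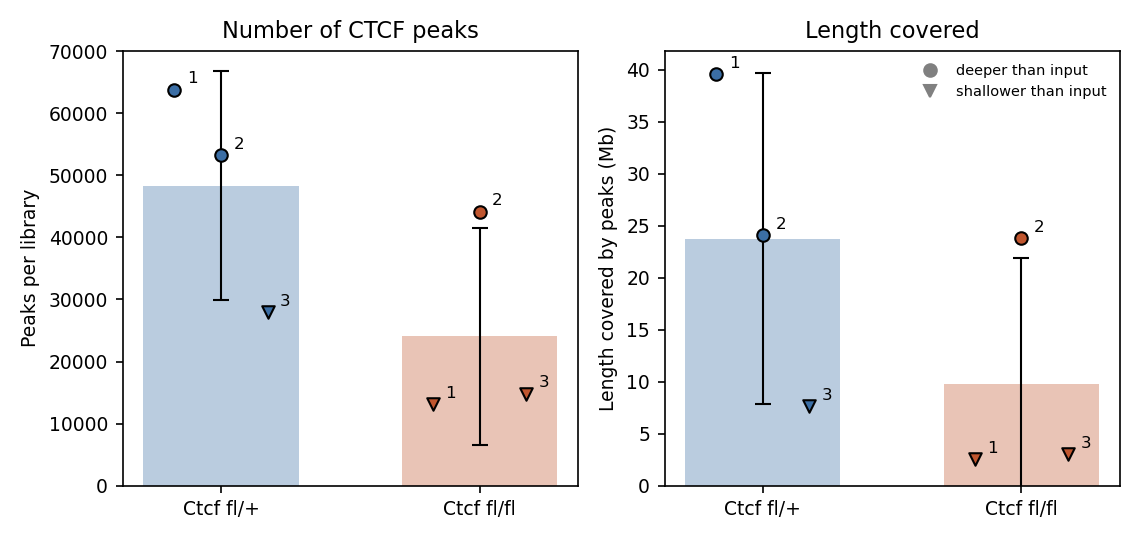
Number of peaks (left axis, count) and length covered by them (right axis, Mb) per library, with bars at the mean and error bars of 1 SD of the 3 libraries of each genotype, ending at 0 where they would pass it. Numbers are replicates, circles are libraries deeper than the input and triangles shallower ones, and fl/fl replicate 2 with 44148 peaks lies near fl/+ replicate 2 with 53217.

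Peaks covered 39.5, 24.1 and 7.64 Mb in fl/+ and 2.52, 23.8 and 3.00 Mb in fl/fl. The ratio of the geometric means was 0.291 (exact two-sided permutation test, p = 0.2). The mean peak width was 620, 453 and 273 bp in fl/+ and 192, 539 and 202 bp in fl/fl, so both the number and the width of the peaks entered this ratio. It was 0.771 within the deeper libraries and 0.36 within the shallower ones. Without fl/fl replicate 2 the ratio was 0.142, and without fl/+ replicate 3 it was 0.183.

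Strongly occupied sites were called in nearly every fl/fl library, and weak sites were mostly missing from 2 of them, the shallowest libraries. Of the 21660 reference sites, which were called in every fl/+ library, fl/fl replicates 1 and 3 called 55.1% and 60.6%, and fl/fl replicate 2 called 99.6%. In the weakest 10% of the reference sites by fl/+ fold enrichment, the shares were 1.29%, 96.5% and 2.03% in fl/fl replicates 1 to 3. In the strongest 10%, they were 99.95%, 100% and 100%. In total 10840 sites, or 50.0% of the reference sites, were called in all 6 libraries. By definition every fl/+ library called all reference sites, so no fl/+ library could show a loss of weak ones here. These shares alone therefore do not tell missed calls at low depth from lost binding. After scaling to equal background, the mean fl/fl share still differed by 66.6 points between the strongest and weakest 10%, against 66.7 as deposited. The lists of fl/fl replicates 1 and 3 then held 13163 and 14585 peaks, against 26256 to 45991 in the other libraries. Depth alone thus does not account for the gap, and what else lowered the calls was not tested.

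**Figure D2:**
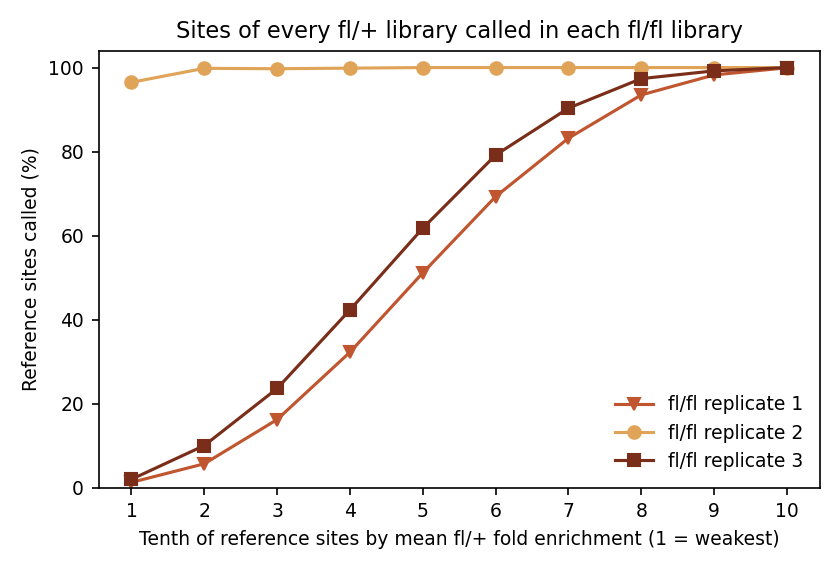
Share of the 21660 reference sites called in each fl/fl library (vertical axis, percent), in 10 bins of the mean fl/+ fold enrichment (horizontal axis, 1 is the weakest). Points are single libraries, and replicates 1 and 3 climb from 1.29% and 2.03% to 99.95% and 100% while replicate 2 stays at or above 96.5%.

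When each fl/+ library was held out in turn, the sites shared by the other fl/+ libraries were found in 84.4% ± 26.7 (SD, n = 3) of cases in the held-out library. They were found in 64.3% ± 26.7 (SD, n = 3) of cases in the fl/fl libraries. The difference was −20.1 percentage points (exact one-sided permutation test, p = 0.1, smallest possible 0.05), which did not exceed the spread between libraries. Among the shallower libraries, sites shared by fl/+ replicates 1 and 2 were found at 53.6% in fl/+ replicate 3, at 29.7% in fl/fl replicate 1 and at 32.8% in fl/fl replicate 3. Among the deeper ones, sites shared by fl/+ replicates 2 and 3 were found at 99.9% in fl/+ replicate 1 and at 99.5% in fl/fl replicate 2. That set holds only sites called in the shallower fl/+ replicate 3. The sites shared by fl/+ replicates 1 and 2 were found at 86.1% in fl/fl replicate 2. With fl/+ replicate 3 left out the difference was −39.2 points, with fl/fl replicate 2 left out −35.5 points, and with fl/fl replicate 1 left out −11.3 points. It was −6.02 points on lists of equal length and −34.3 points with a reciprocal overlap of 50%.

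Sites present in every fl/+ and absent from every fl/fl library were rare, and most were autosomal, with a larger X-linked share than among other reference sites. There were 80 of them, of which 16 lay on chromosome X (20%, against 2.49% of the other reference sites). The class can hold only sites missing from fl/fl replicate 2, which called 21571 of the 21660 reference sites. That library called 95.5% of the 553 reference sites on chromosome X, against 99.6% of all, so the X-linked share rests on that library. The 10 strongest of the 80 included 3 in Firre, which encodes a nuclear RNA of the X chromosome: 50622746 to 50623445, 50611757 to 50612544 and 50599832 to 50600571. The geometric means of their fl/+ fold enrichments were 18.2, 13.1 and 11.4. A pair of sites lay in 4933407K13Rik, annotated with the synonym Dxz4, at 75759022 to 75759316 (15.5) and 75749327 to 75749610 (15.3). Another pair lay in Dmd, the dystrophin gene, at 83875024 to 83875893 (20.6) and 84001252 to 84001737 (10.6). The last X-linked site, at 24153307 to 24153618 (12.3), had Gm4985 as its nearest gene, 194523 bp from its middle. The autosomal ones were a site on chromosome 8 at 83624358 to 83625364 (12), 12207 bp from Dnajb1, and a site in Susd6 on chromosome 12 at 80801383 to 80801786 (10.4).

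No site was called in every fl/fl and no fl/+ library. The highest count for any other split of the 6 libraries was 13040, for the deeper libraries against the shallower ones, and the next was 25. The fl/+ count depended on single libraries: it was 7466 without fl/fl replicate 2, 5616 without fl/+ replicate 3, 182 without fl/+ replicate 1 and 150 without fl/+ replicate 2. It was 1306 when summits within 100 bp were matched instead of peaks.

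**Figure D3:**
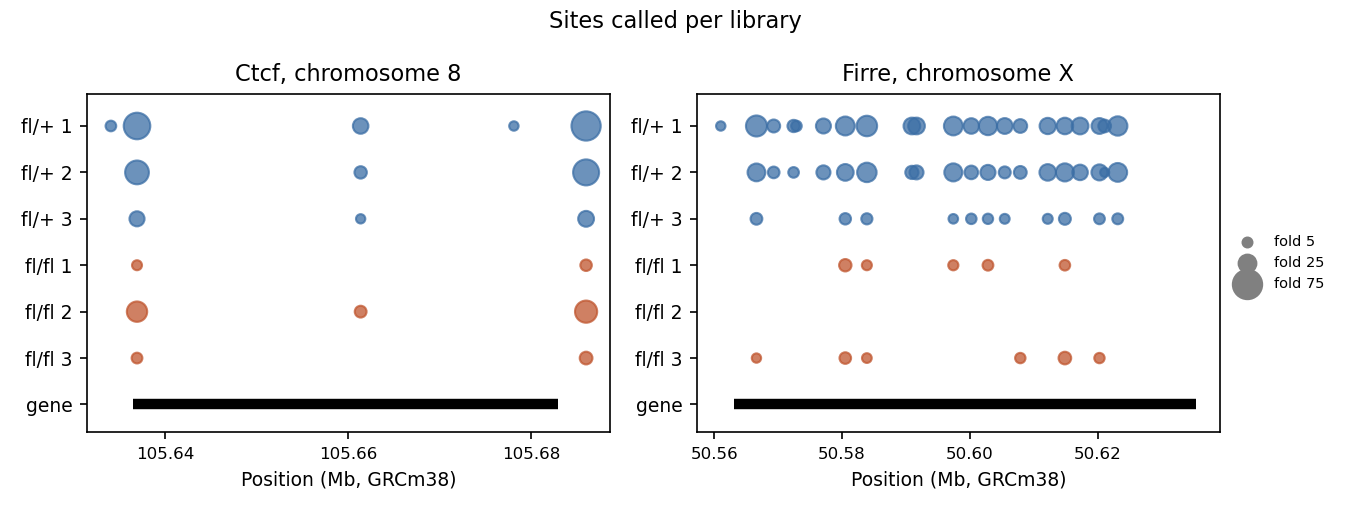
Sites called per library along Ctcf on chromosome 8 (left) and Firre on chromosome X (right), with position in Mb on the horizontal axis and 1 library per line. The size of a circle is the authors' fold enrichment in that list, and fl/fl replicate 2 has 3 sites at Ctcf and 0 of the 21 sites at Firre.

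The 5 strongest sites called in all 6 libraries were mostly outside genes. They lay at 129724038 to 129725825 on chromosome 5, 84 bp from Nipsnap2 (geometric mean fold enrichment 94.4), and at 111289249 to 111290595 on chromosome 9, 10828 bp from Epm2aip1 (89.5). The others were a site in Gm40715 on chromosome 10 at 79924764 to 79926326 (83.6), a site on chromosome 18 at 76377363 to 76380832, 67349 bp from Smad2 (78.1), and a site on chromosome 7 at 137477413 to 137479359, 8754 bp from Glrx3 (77.8).

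On lists of equal length, libraries of the same genotype shared slightly more sites on average than libraries of different genotype, but the sign depended on single libraries. The mean Jaccard index of the top 13168 peaks was 82.6% within and 80.2% between genotypes, a difference of 2.36 points (exact one-sided permutation test over 10 splits, p = 0.1, the smallest possible). It was 87.7% among fl/+ and 77.4% among fl/fl libraries. The difference was −0.294, −0.547 and 0.203 points without fl/+ replicates 1, 2 and 3, and 3.55, 7.51 and 3.85 points without fl/fl replicates 1, 2 and 3. With a reciprocal overlap of 50% it was −2.38 points.

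Reference sites at genes of B cell identity were called in fl/fl about as often as random reference sites of the same strength. In this and the following gene lists, a two-sided test against 10000 random sets is given, and as sites are not replicates it describes these libraries only. Their 38 reference sites, at 13 of the 16 genes, were called at 70.2% per fl/fl library, against 70.9% in random sets of the same strength (adjusted p = 0.992). The strongest sites of Cd79a, part of the B cell receptor, and of Cd19, its co-receptor, were called in all 6 libraries, with mean fl/+ fold enrichments of 77.1 and 69.0. At Cd79a and at Ikzf3, which encodes Aiolos, only 1 of 3 sites was called in fl/fl replicates 1 and 3. The immunoglobulin loci held 75 reference sites, called at 56.9% against 59.3% (adjusted p = 0.776). In fl/fl replicates 1 and 3, 14 and 18 of the 43 sites of Igh were called, and 8 and 11 of the 28 sites of Igk. The 4 sites of Igl were all called in fl/fl replicate 2, with 1 of them called in each other fl/fl library.

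The germinal centre list had 19 reference sites called at 75.4% against 80.2% (adjusted p = 0.715). The strongest lay at Aicda, the deaminase of antibody diversification, and at Ung, a DNA glycosylase, with mean fl/+ fold enrichments of 89.0 and 87.8. At Mybl1, 1 of 2 sites was called in fl/fl replicate 1 and 0 in replicate 3. The plasma cell list had 10 sites called at 63.3% against 60.8% (adjusted p = 0.992). Prdm1, which encodes Blimp-1, had 1 site called in all 6 libraries, while the single sites of Sdc1 and Tnfrsf17 were called in fl/fl replicate 2 alone among fl/fl libraries. The B cell activation list had 10 sites called at 66.7% against 71.0% (adjusted p = 0.961). The strongest sites of Cd40 and Nr4a1 were called in all 6 libraries, and the single site of Nfkb1 in fl/fl replicate 2 alone among fl/fl libraries.

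Genes of CTCF and its partner cohesin had 16 reference sites called at 81.3% against 82.3% (adjusted p = 0.992). The strongest were at Stag1 and Stag2, which encode cohesin subunits, with mean fl/+ fold enrichments of 68.7 and 65.5, and both were called in all 6 libraries. At Nipbl, the cohesin loader, 1, 3 and 2 of 3 sites were called in fl/fl replicates 1 to 3. The cell cycle and Myc list had 15 sites called at 82.2% against 86.1% (adjusted p = 0.841), with the strongest sites at Cdkn1a and Cdk4. The housekeeping list had 17 sites called at 58.8% against 65.5% (adjusted p = 0.715). Actb had a site called in all 6 libraries. The single sites of Gapdh and Ubc were called in fl/fl replicate 2 alone among fl/fl libraries.

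At classical CTCF-bound clusters, no list differed from its random sets past an adjusted p of 0.05. The imprinted list had 8 reference sites called at 54.2% against 58.1% (adjusted p = 0.992). The site at H19 and the site at Peg10 were each called in fl/fl replicate 2 alone among fl/fl libraries, while the site at Nnat was called in all 6 libraries. The Hox clusters had 18 sites called at 75.9% against 76.4% (adjusted p = 1). The strongest was a single site within 10 kb of both Hoxa10 and Hoxa3. The single sites at Hoxb13 and Hoxd4 were called in fl/fl replicate 2 alone among fl/fl libraries. The protocadherin clusters had 8 sites called at 54.2% against 56.2% (adjusted p = 1). The strongest was a site shared by overlapping genes, Pcdhga1 and Pcdhga10 among them. The single site at Pcdhgc3 was called in fl/fl replicate 2 alone among fl/fl libraries.

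The X inactivation list was the only list with reference sites missing from fl/fl replicate 2. Its 18 sites were called at 38.9%, 38.9% and 50.0% in fl/fl replicates 1 to 3, with a mean of 42.6% against 53.2% in matched sets (random-set test, n = 18 sites, p = 0.0181, adjusted p = 0.193). Firre had 11 reference sites, of which 5, 0 and 5 were called in fl/fl replicates 1 to 3. The strongest site of Xist and Tsix, the antisense pair of the X inactivation centre, was called in all 6 libraries. The difference from the matched sets was −10.6 points, but 14.4 points without fl/fl replicate 2. It was −16.8, −21.8 and −24.4 points without fl/+ replicate 3, fl/fl replicate 1 and fl/fl replicate 3, each with an adjusted p of 0.0016. Over all alternatives the adjusted p ranged from 0.0016 to 0.364.

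Lists of other cell types gave no adjusted p under 0.05 either. The T cell list had 14 sites called at 71.4% against 64.6% (adjusted p = 0.715), and the erythroid list 8 sites called at 75% against 66.6% (adjusted p = 0.769). The myeloid list had 7 sites called at 85.7% against 89.3% (adjusted p = 0.992). The liver and neuron list had 12 sites called at 61.1% against 73.9% (random-set test, n = 12 sites, p = 0.0241, adjusted p = 0.193), among them 8 at Rbfox3, a neuronal splicing factor. Its difference of −12.8 points was −2.77 points without fl/fl replicate 1, −8.34 points without fl/+ replicate 3 and −19.5 points without fl/fl replicate 2. Thus 0 of the 16 lists passed the adjusted threshold in the random-set test, and 2 had an unadjusted p under 0.05. The count was 3 without fl/fl replicate 3 (X inactivation, T cell, and liver and neuron), and 1 (X inactivation) without fl/+ replicate 3 or without fl/fl replicate 1.

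**Figure D4:**
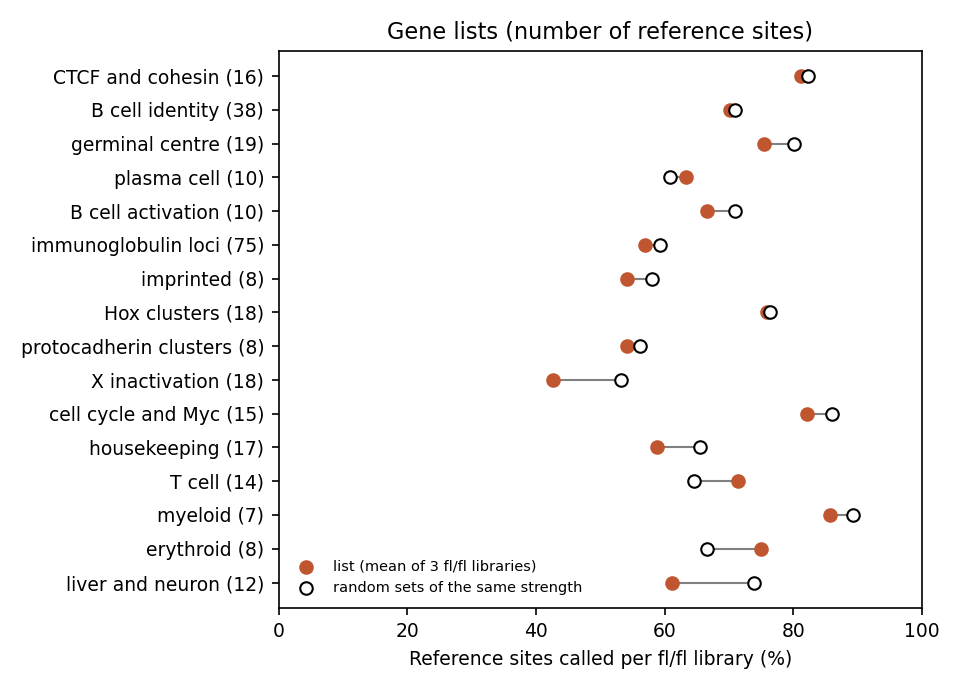
Share of the reference sites of each gene list called per fl/fl library (horizontal axis, percent), as the mean of the 3 fl/fl libraries (filled) and as the mean of 10000 random sets of the same strength (open). The number of sites is in brackets, and the X inactivation list (42.6% against 53.2%) and the liver and neuron list (61.1% against 73.9%) lie farthest below their random sets.

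The placement of peaks along genes did not differ between the genotypes beyond the spread of the libraries. The share of peaks with a summit within 1 kb of a gene end was 21.9% ± 2.5 (SD, n = 3) in fl/+ and 20.7% ± 1.54 (SD, n = 3) in fl/fl, a difference of −1.17 points (exact two-sided permutation test, p = 0.6). It was −0.802 points within the deeper and 0.715 points within the shallower libraries. Without fl/+ replicate 1 it was −0.101, without fl/+ replicate 3 −2.55, without fl/fl replicate 2 −2.04 and without fl/fl replicate 3 −0.578 points. The share inside protein-coding genes was 52.6% ± 2.53 (SD, n = 3) in fl/+ and 49.2% ± 3.63 (SD, n = 3) in fl/fl (exact two-sided permutation test, p = 0.3).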

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

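The test below was chosen after the data had been seen. The list of fl/fl replicate 2 held 295 peaks on the human chromosomes of the combined reference, a part of the lists that no comparison used. The fl/+ lists held 6, 1 and 2 such peaks, and the lists of fl/fl replicates 1 and 3 held 1 and 3.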

How the results depend on the processing

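The settings named as added in this paragraph were chosen after the data had been seen: every summit counted, the depth classes, and all settings of the relative signal, of retention by strength and of the X inactivation and liver and neuron lists taken singly. The ratios of peak number and covered length stayed under 1 and recovery stayed negative (−39.2 to −6.02 points, the latter on lists of equal length) under all settings tried, with p from 0.1 to 0.5, in tests that could not pass 0.05. The ratio of peak numbers ranged from 0.307 to 0.561 when a library was left out and was 0.5035 after scaling to equal background. The sites called in every fl/+ and no fl/fl library numbered 27 with a −log10 q of at least 5, 49 with a fold enrichment of at least 5, 29 with a reciprocal overlap of 50%, 1306 with summits within 100 bp and 123 on lists of equal length. They ranged from 83 to 7466 with a library left out. The mirror class numbered 69 on lists of equal length and 0 to 1 with a library left out. The overlap difference was −2.38 points with the reciprocal overlap and 5.56 points on lists cut to 0.5 of the shortest length. It ranged from −0.547 to 7.51 points with a library left out. The difference in the share near gene ends was 0.234 points at 5 kb. On lists of equal length, 2 gene lists passed, X inactivation (4 sites, −36.7 points) and liver and neuron (7 sites, −26.6 points), and 0 to 3 did with a library left out. The X inactivation difference ranged from −24.4 to 14.4 points with a library left out, the highest without fl/fl replicate 2. The cause of these changes was not tested. Under the replicate block, same-numbered pairs gave ratios of 0.45 and 0.291 for peak number and covered length, −22.0 points for recovery and −1.17 points for gene ends, with exact sign-flip permutation p from 0.25 to 0.75. The smallest p of 3 pairs is 0.25, so the block could not change a call. For relative signal, the changed summits numbered 579 with quantile normalization, 1447 with the replicate block, 753 with the depth class in the model, 118 at summits with at least 15 fragments in every library, and 0 to 2590 with a library left out. The motif share and its alternatives were not run. Neither the X inactivation list nor the liver and neuron list had a reference site under the reciprocal overlap.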

Other observations

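All tests in this part were chosen after the data had been seen. At a minority of the summits called in every library, relative CTCF signal differed between the genotypes, with a count that depended strongly on the setting. Before centring, the median signal at these summits, fl/fl over fl/+, was 0.426 (exact two-sided permutation test, p = 0.2), 0.75 within the deeper and 0.548 within the shallower libraries, so higher and lower here are relative to each library's median. With limma on median-centred log2 fragments per depth, 199 of 11498 summits passed an adjusted p of 0.05, 175 relatively higher and 24 relatively lower in fl/fl. With quantile normalization there were 579, of which 274 were higher and 305 lower, so the balance of directions depends on the scaling. There were 1447 with the replicate block (1080 higher, 367 lower) and 118 among the 7479 summits with at least 15 fragments in every library (75 higher, 43 lower). The median at the tested summits was 206, 149 and 42 fragments in fl/+ replicates 1 to 3. It was 19 and 23 in fl/fl replicates 1 and 3. Summits too weak to be called there, or to hold 15 fragments, were left out, so these filters also shape the counts of higher and lower. Summits called under both scalings included one in Mid1 on chromosome X (169979253 to 169979374), higher by 1.31 ± 0.22 (SE) on the log2 scale. Another lay in Ptpn18 on chromosome 1 (34462946 to 34463058), higher by 0.89 ± 0.17 (SE). Relatively lower ones included a summit in Scara5 on chromosome 14 (65741969 to 65742100), at −0.90 ± 0.19 (SE), and one 7064 bp from Nedd9 on chromosome 13 (41302794 to 41302909), at −0.77 ± 0.18 (SE). These genes were chosen after their values were seen.

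Under quantile normalization, relatively lower summits lay in genes more often than relatively higher ones: 54.8% of the lower and 32.8% of the higher summits lay in protein-coding genes, against 46.5% of all tested (Fisher's exact test of lower against higher, adjusted p = 2.45e-07, with summits not being replicates). Among summits called under both scalings, the shares were 47.8% of the 23 lower and 30.2% of the 139 higher ones, so the lower ones lay near the share of all tested. Among reference sites, those outside protein-coding genes were called at 73.9% per fl/fl library against 72.0% in sets matched on strength, and those inside at 69.6% against 71.6%. Both had p = 0.0001 (random-set test, n = 10807 and n = 10853 sites), the smallest that 10000 random sets can give. Each of these classes holds the sites that the other leaves out, and its random sets came from the other, so the tests are not independent. Per library, without matching on strength, 58.4% outside and 51.8% inside were called in fl/fl replicate 1, and 63.7% and 57.5% in replicate 3. Replicate 2 called 99.6% in both, nearly all sites, so its shares do not tell whether it had a gap. Sites within 1 kb of a gene end were called at 72.9% against 73.6% (random-set test, n = 4203 sites, adjusted p = 0.0145). All reference sites on chromosome X were called at 60.5% against 62.1% (random-set test, n = 553 sites, adjusted p = 0.0558).

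Of the 10 splits of the 6 libraries, 1 gave as many as 199 changed summits, the real one, and the highest of the others gave 1, but with 10 splits no share under 0.05 can be reached. The split by depth gave 0, yet 2213 summits had an unadjusted p under 0.05 in it, against 3212 in the real split and 151 to 644 in the others, so relative signal also went with depth. With the depth class in the limma model 753 summits were changed (736 higher, 17 lower), so the depth class did not take the difference away. The model could not take up differences within a class. Among the shallower libraries the median was 42 fragments in fl/+ replicate 3 and 19 and 23 in fl/fl replicates 1 and 3. An effect of few fragments and of the calling limit therefore stays open. The count was 0 without fl/+ replicate 3, fl/fl replicate 1 or fl/fl replicate 3, and it was 50 without fl/+ replicate 1, 18 without fl/+ replicate 2 and 2590 without fl/fl replicate 2. The labels give no batch, so a preparation batch that followed the genotypes stays open, and so does the genotype itself.

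The list of fl/fl replicate 2 was about as long as the fl/+ lists, at 3.15 times the mean of the other fl/fl lists. It was still 2.65 times that mean after scaling to equal background, which takes in depth and fragment length, so depth does not account for it alone. Its Jaccard index on lists of equal length was 84.1% to 87.8% with fl/+ libraries, against 77.8% and 79.3% with fl/fl replicates 1 and 3, but fl/fl replicates 1 and 3 also shared less with each other (75.3%) than with fl/+ libraries (75.9% to 78.1%), so this index does not separate the genotypes, and its signal correlated over summits at 0.885, 0.882 and 0.839 with fl/+ replicates 1 to 3, against 0.841 and 0.853. Against a fl/+ library under a fl/fl label, no fl/+ library correlated above 0.757 with fl/fl replicates 1 or 3. Its quantile-normalized signal difference from a fl/+ library also correlated with that of fl/fl replicates 1 and 3 at 0.278 to 0.491. With fl/+ libraries in its place the values were −0.135 to 0.135, in pairs of opposite sign because each difference was taken both ways. With median centring it was 0.637 and 0.606 with fl/+ replicates 1 and 2 subtracted, against 0.406 at most for fl/+ libraries. With fl/+ replicate 3 subtracted it was 0.113, within the fl/+ range of −0.406 to 0.406. Only with quantile normalization did it thus lie above the fl/+ range for every fl/+ library subtracted. The amount of CTCF left in these cells, a mixture of cells and the efficiency of the immunoprecipitation were not tested and stay open.

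Of the reference sites, fl/fl replicate 2 called 0 of 11 at Firre, where the shallower fl/fl replicates 1 and 3 called 5 each, while the 2 at Dxz4 were called in no fl/fl library. Reference sites of the strength of these 13 were called at 99.5% in fl/fl replicate 2, so depth does not account for the gap there. In fl/fl replicates 1 and 3 the direction was the opposite: the 13 sites were called at 38.5% in each, against 13.2% and 18.8% of matched sites. A candidate explanation is an animal without an inactive X chromosome, since both loci are known to bind CTCF on that chromosome. At the 174 summits of chromosome X, the quantile-normalized log2 signal of fl/fl replicate 2 relative to the other libraries lay at −0.27 (autosomes −0.02 to 0.03). X also left the range of the autosomes in other libraries, at −0.05 and −0.08 in fl/+ replicates 1 and 2 and 0.22 in fl/fl replicates 1 and 3. With median centring, X lay at −0.24 in fl/fl replicate 2 and at 0.09 and 0.07 in fl/fl replicates 1 and 3. In fl/+ replicates 1 to 3 it then lay at 0.11, 0.06 and −0.07. Without normalization X lay below the autosomes by nearly as much in fl/+ replicate 3 (−0.53) as in fl/fl replicate 2 (−0.60), so the hypothesis stays open, and the labels give no sex.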
